A study of Phaseolus vulgaris with 21 samples.

How the data were processed

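The data are RNA-seq profiles of 7 tissues of common bean (Phaseolus vulgaris) cultivar Blue Lake 274, with 3 libraries per tissue. Plants were grown with 16 h of light and 8 h of darkness at 250 umol per square metre per second and 23 °C, per the labels' protocols. Nectaries were dissected by hand and their RNA was extracted at once. The libraries were pooled over 2 lanes and sequenced as paired-end 50 bp reads, per the labels' protocols.

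The authors counted the bean reads on soybean RefSeq transcripts, per the file headers and the labels' protocols, so each row is named by a soybean transcript and not by a bean gene. The read mapper and its settings are not given in the sources used here. The submitters' processing notes name DESeq, with no version and no role. The deposited values are a score, normalized read counts rescaled by the upper quartile and rounded to whole numbers by the authors, per the file headers. They are therefore not raw counts. The deposited table held 6359 rows, 21 columns of library values and 20 columns of the authors' means, SDs and calls. The authors' SDs matched those recomputed from the library columns, and their means lay within 0.6667 of the recomputed ones.

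Several properties of the table limit what can be measured. A bean transcript that matches several soybean copies may have been split among them or assigned to 1 of them, so members of a gene family are uncertain as single genes. The lowest value in library 1 of the secretory floral nectary was 1, while every other library held zeros, so the deposited table appears to have been filtered on that library, although no header or label says so. Transcripts of leaf or extrafloral nectary that are outside the table are not analysed here. Library sums over the table ran from 2616502 to 4270943. From the spacing of low values, 1 read was estimated to be worth 0.794 to 1.322 units, which puts the reads behind a library at 2709940 to 4455965. A value of a few units then rests on a few reads, so calls between values near 0 rest on few reads too. Of the rows, 2229 are described as uncharacterized, and 5757 carry an Arabidopsis match in the table, 1133 of them several. Genome coordinates are not used here, since the rows are transcripts of another species than the one sequenced.

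The design was written before the data were examined, with one branch for counts and one for normalized values. Because the values are normalized, the branch for normalized values was used, and the count models planned as alternatives were not run. Values were transformed as log2(value + 1), with a pseudocount of 1, so fold changes of low transcripts are understated. Rows with a mean of at least 1 were tested, which kept 6351 and left out 8. All 21 libraries entered 1 linear model with a mean for each of 7 groups and 14 residual degrees of freedom. Contrasts were tested two-sided with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. The contrast of extrafloral nectaries with leaf weights the 2 extrafloral tissues equally, and that of floral nectaries with leaf weights the 4 stages equally. An F test asked which transcripts differed among the 4 floral stages.

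Gene lists were fixed before the data were examined, and a row belonged to a list where the table pairs it with a listed Arabidopsis locus. The lists cover nectar regulators and secretion genes, sugar transport, sucrose metabolism, starch synthesis and breakdown, photosystems and antenna, the Calvin cycle, jasmonate, auxin, phenylpropanoids, defence and nectar proteins, floral organ identity, primary wall expansion, senescence, exocytosis, proton pumps, amino acids and nitrogen, hypoxia, the cell cycle and cytosolic ribosomal proteins. Further lists stand for other cell types that a dissected piece could hold (pollen, carpel and ovule, phloem, xylem, epidermis), for handling (heat shock, rapid wound response) and for time of day (morning and evening clock genes). A list of guard cell genes matched 0 rows. Lists with at least 3 rows, 24 in number, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists, and again with the correlation estimated from the data. No list was taken from these samples.

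Named genes followed a rule written before the data were examined. In each comparison they are the 5 most increased and 5 most decreased transcripts that passed the test, had no overlap between the libraries of the sides compared, and had a higher-side group mean at or above the 75th percentile of row means, 493.36. Added to these are up to 2 members of each list with the smallest adjusted p, and the members of the list of nectar regulators and secretion genes in every comparison. A gene named in one comparison may be given in others.

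The pipeline was tested on simulated data, in which 200 rows were changed by known folds. For the extrafloral nectaries against leaf, it recovered 25.4% of rows changed 1.5-fold, 55.2% of those changed 2-fold and 90.9% of those changed 4-fold, with 4 false calls among 118 over 6350 rows. The other contrasts had 6349 rows. For stem against leaf extrafloral nectaries, these shares were 22.4%, 46.3% and 86.4%, with 3 false calls among 106. For the secretory stage against pre2 they were 13.4%, 47.8% and 95.5%, with 5 among 109. For floral nectaries against leaf they were 26.9%, 71.6% and 100%, with 7 among 139. These figures hold for the simulated spread only.

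Alternatives planned before the data were examined were rescaling by median ratios (with and without photosynthesis rows), no filter and a filter at a mean of 10, pseudocounts of 0.1 and 10, a fit to only the libraries compared, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum, leaving out each library in turn, and the secretory stage alone in place of the 4 stages. Alternatives chosen after seeing the data were robust variance moderation, rescaling to equal upper quartiles over the table, leaving out both stem extrafloral libraries numbered 2 and 3, leaving out both extrafloral libraries numbered 3, and list membership by description. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.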

Results

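Tissues of common bean, 7 in number, were profiled with 3 libraries each: leaf, the extrafloral nectaries (EFN) where terminal trifoliate leaves attach (leaf EFN), those found on the stem where lateral trifoliate leaves attach (stem EFN), and floral nectaries (FN) at 4 stages. The floral stages are pre1 at 24 h before anthesis, pre2 at 12 h before, the secretory stage at full anthesis 3 h after dawn, and post 12 h after that. Values are the authors' normalized values on soybean transcripts, so a gene named here is the soybean transcript that bean reads matched, and close copies may share reads. Changes are log2 fold changes of the normalized value + 1, and levels are mean ± SD with n = 3 in each group. P-values are from limma and measure only within-group spread pooled over all 7 groups, which may be technical, since the labels do not mention separate plants. Only library 1 of the secretory stage has no value at 0, so the deposited table appears filtered on it. Transcripts outside the table are not analysed here. Of 6359 rows, 6351 were tested. Tests, lists and named genes were chosen before the data were examined unless stated otherwise.

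Floral nectaries stood apart from leaf and both extrafloral nectaries along the first principal component, which held 72.58% of the variance over 1000 transcripts. Floral stages were spread along the next component, with 13.72%, from pre1 at the low end to post at the high end. Leaf parted from the extrafloral nectaries on component 3, with 5.578%. Within groups, correlations between libraries ran from 0.938 in stem EFN to 0.9859 in the secretory stage. A single transcript, LOC100101840, held 8.995% of all values in library 3 of leaf EFN and 12.09% in library 3 of stem EFN.

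**Figure D1:**
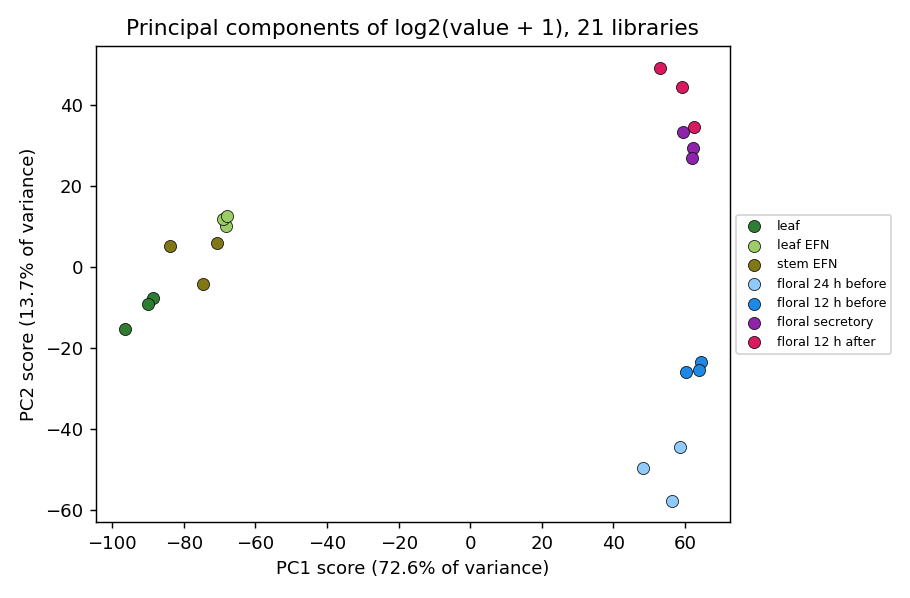
Principal components 1 and 2 of the 1000 transcripts, with the percent of variance on each axis; each point is a library, coloured by its group of 3. Floral nectary libraries lie at one end of the first component, which holds 72.58% of the variance, and floral stages are spread along the next one, with 13.72%.

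**Figure D2:**
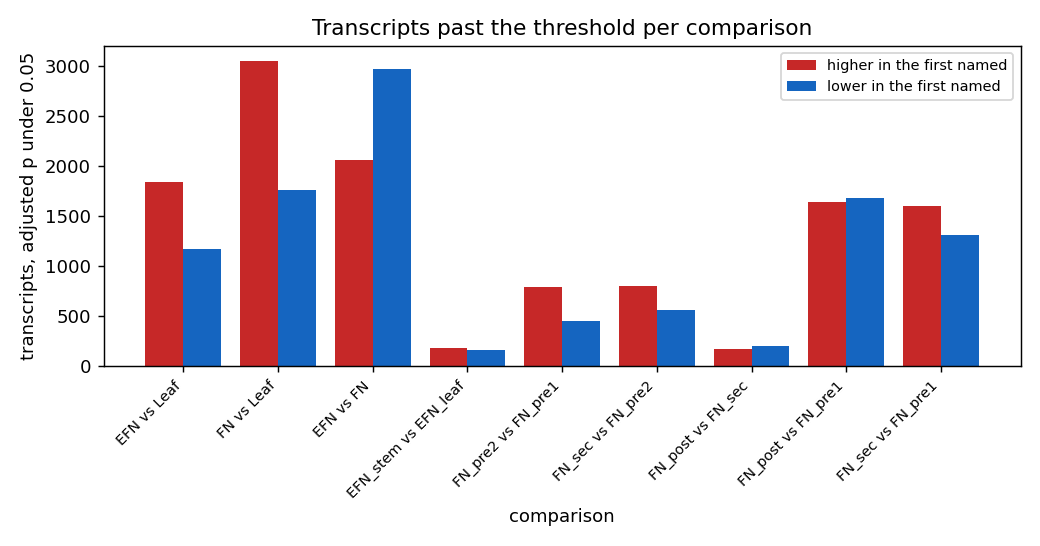
Number of transcripts that were higher and lower at an adjusted p under 0.05 in limma, as bars, for 9 comparisons. Totals of both were highest for extrafloral against floral nectaries, at 5033, and lowest for stem against leaf extrafloral nectaries, at 341.

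Extrafloral nectaries had higher transcripts than leaf for a lectin-domain protein, a lipoxygenase, a Kunitz protease inhibitor, the jasmonate repressors TIFY10A and JAZ1, and 2 cell wall invertases. Nitrate reductase, asparagine synthetase, GIGANTEA and PRR37 clock transcripts were lower. No hour is given for leaf or extrafloral samples, so time of day may enter their comparisons. Lectin-domain LOC100305701 rose most among the named genes. SWEET14-like transcripts were detected in both nectaries and listed at 0 in leaf. All 20 photosystem and antenna transcripts were lower.

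In extrafloral nectaries the lectin-domain transcript LOC100305701 rose by 12.98 (SE 0.578, adjusted p = 5.32e-12), from 1.67 ± 1.53 in leaf to 11544 ± 1286 in leaf EFN and 34169 ± 19010 in stem EFN. Lipoxygenase L-5 (VLXB) was listed at 0 in leaf and averaged 1499 ± 841 in leaf EFN and 3730.3 ± 5245 in stem EFN (adjusted p = 4.9e-10), where libraries 1, 2 and 3 held 657, 748 and 9786. The 31 kDa acid phosphatase LOC547820, of the vegetative storage type, was also listed at 0 in leaf, with 1118 ± 1046 in leaf EFN and 6038 ± 10280 in stem EFN (adjusted p = 2.66e-05), and its stem EFN libraries held 45, 165 and 17904, so library 3 sets both stem means. Cytochrome P450 71A1-like LOC100803384 rose by 8.44 (SE 0.37, adjusted p = 5.32e-12) and the Kunitz protease inhibitor LOC100527288 by 8.14 (SE 0.533, adjusted p = 1.21e-09). The polygalacturonase inhibitor LOC100783399, which acts against wall-degrading enzymes of pathogens, rose by 4.65 (adjusted p = 0.000129). The defence and nectar protein list had 3 of 7 higher and 1 lower (adjusted over the list alone, 3 and 1), with camera adjusted p = 0.87.

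Among sugar carriers, SWEET14-like LOC100810962 averaged 93 ± 21.6 in leaf EFN and 248 ± 118 in stem EFN (adjusted p = 1.07e-12), and the SWEET family member LOC102669242 39.7 ± 24.6 and 14 ± 7 (adjusted p = 7.24e-08); both were listed at 0 in leaf. SWEET13-like LOC100810946, which matches Arabidopsis SWEET9 and SWEET11, fell by 1.06 (SE 0.398, adjusted p = 0.0358), a call lost without leaf library 1 (0.0898), leaf library 2 (0.146), leaf EFN library 1 (0.0522), leaf EFN library 2 (0.09) or stem EFN library 3 (0.053). Cell wall invertase LOC100777418, whose Arabidopsis relative CWINV4 is needed for nectar, rose by 2.47 (SE 0.486, adjusted p = 0.000396), and the invertase CWINV by 1.43 (SE 0.228, adjusted p = 5.2e-05). Sucrose synthase SS rose by 1.42 (adjusted p = 7.92e-05). The sugar transport list had 3 of 7 higher and 3 lower (adjusted over the list alone, 3 and 3), with camera adjusted p = 0.348. Sucrose metabolism had 5 of 8 higher and 0 lower (adjusted over the list alone, 5 and 0), with camera adjusted p = 0.177.

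The MYB regulators of nectar genes were at low values in the extrafloral nectaries. The MYB305-like transcript LOC100816972 was listed at 0 in leaf and averaged 1.33 ± 0.577 in leaf EFN and 11.7 ± 10.1 in stem EFN (adjusted p = 0.00106; 0.0684 with a pseudocount of 10). Its stem EFN values were 1, 13 and 21 in libraries 1, 2 and 3, and those of MYB98 1, 7 and 6, so the stem levels come from libraries 2 and 3, which held low values of many floral transcripts. With these libraries left out, an alternative chosen after seeing the data, both calls held, but on values of 1, 1 and 2 in leaf EFN and 1 in stem EFN for LOC100816972, and 1, 0 and 1 and 1 for MYB98. MYB98, listed at 0 in leaf, averaged 0.667 ± 0.577 and 4.67 ± 3.21 (adjusted p = 0.00112; 0.121 with a pseudocount of 10 and 0.0948 in a fit to only the libraries compared). MYB182 did not pass (adjusted p = 0.0969), although it did without stem EFN library 1 (0.000321). The CRABS CLAW match LOC100500026, which directs nectary development in Arabidopsis, was listed at 0 in leaf and both extrafloral nectaries. The BLADE-ON-PETIOLE match LOC100816086, also of nectary development, fell by 0.94 (SE 0.164, adjusted p = 0.000133). Leaf averaged 166, leaf EFN 56.7 and stem EFN 133. The nectar list, of regulators, cell wall invertases and SWEET13-like LOC100810946, had 4 of 8 higher and 2 lower (adjusted over the list alone, 4 and 2), with camera adjusted p = 0.438.

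Jasmonate repressors TIFY10A (LOC100801449) and JAZ1 (LOC100306332) rose by 4.103 (SE 0.309, adjusted p = 8.2e-09) and 3.51 (SE 0.281, adjusted p = 1.7e-08). The jasmonate list had 7 of 12 higher and 3 lower (adjusted over the list alone, 7 and 4), with camera adjusted p = 0.192. Expansin EXP4, a wall-loosening protein, rose by 4.47 (adjusted p = 1.52e-05). The primary wall list had 5 of 10 higher and 1 lower (adjusted over the list alone, 6 and 1). Proline dehydrogenase PDH rose by 4.39 (adjusted p = 8.84e-08) and cytosolic glutamine synthetase GS1alpha by 2.19 (adjusted p = 1.18e-07), while inducible nitrate reductase INR2 and asparagine synthetases AS2 and AS1 were lower, at -4.69 (SE 0.489, adjusted p = 4.34e-07), -4.23 (adjusted p = 4.12e-07) and -3.28 (adjusted p = 1.25e-05). The amino acid and nitrogen list had 5 of 12 higher and 4 lower (adjusted over the list alone, 5 and 5). The ACC oxidase-like LOC100807427, for the last step of ethylene synthesis, the germin-like LOC100500326 and the P450 706A match LOC102662729 were lower, at -4.402 (adjusted p = 4.37e-06), -4.26 (adjusted p = 0.000164) and -3.98 (adjusted p = 4.11e-08). Vesicle membrane protein VAMP726-like LOC100804314 rose by 1.595 (adjusted p = 4.27e-07). The exocytosis list had 7 of 11 higher and 0 lower (adjusted over the list alone, 7 and 0), with camera adjusted p = 0.0919. SEPALLATA1-like LOC100788427_XM_003552561.3 rose by 2.97 (adjusted p = 6.05e-07). Floral organ identity had 5 of 14 higher and 3 lower (adjusted over the list alone, 5 and 3).

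Photosystem and antenna transcripts had a median of -2.13. The list had 0 of 20 higher and 20 lower (adjusted over the list alone, 0 and 20; camera adjusted p = 1.48e-15 and adjusted p = 0.29 with an estimated correlation). The chlorophyll-binding CAB3 and LOC100808379 stood at -3.32 (SE 0.236, adjusted p = 3.86e-09) and -2.77 (SE 0.223, adjusted p = 1.78e-08). The Calvin cycle had 0 of 6 higher and 5 lower (adjusted over the list alone, 0 and 5; camera adjusted p = 0.00337 and adjusted p = 0.367 with an estimated correlation), among them glyceraldehyde-3-phosphate dehydrogenase LOC732655 at -2.43 (adjusted p = 2.26e-06) and aldolase LOC100786504 at -1.79 (adjusted p = 1.11e-05). Alpha-amylase-like LOC100813490 and branching enzyme LOC100785968 were lower, at -1.88 (adjusted p = 5.06e-07) and -1.38 (adjusted p = 2.11e-05). Starch breakdown had 3 of 12 higher and 5 lower (adjusted over the list alone, 3 and 5) and starch synthesis 1 of 5 higher and 3 lower (adjusted over the list alone, 1 and 3). Morning clock genes had 1 of 9 higher and 7 lower (adjusted over the list alone, 1 and 7; camera adjusted p = 0.0136 and adjusted p = 0.449 with an estimated correlation), including PRR37-like LOC100785796 at -1.92 (adjusted p = 1.1e-05). Evening clock genes had 1 of 7 higher and 4 lower (adjusted over the list alone, 1 and 4; camera adjusted p = 0.0395 and adjusted p = 0.449 with an estimated correlation), including GIGANTEA (LOC100779044) at -2.22 (adjusted p = 4.37e-07). The auxin list had 3 of 13 higher and 4 lower (adjusted over the list alone, 3 and 4), with SLR1 at -2.33 (adjusted p = 7.02e-05).

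Some members of the lists for handling and other cell types were called as well, while 47.39% of all transcripts were called in this comparison. Heat shock genes had 4 of 7 higher and 0 lower (adjusted over the list alone, 4 and 0) and the rapid wound response 4 of 7 higher and 1 lower (adjusted over the list alone, 4 and 1), with camera adjusted p = 0.192 and 0.252; HSP83 (LOC100811234) rose by 1.38 (adjusted p = 1.59e-06) and the ZAT10-like STF-3 by 3.76 (adjusted p = 6.11e-06). Carpel and ovule genes had 3 of 4 higher and 0 lower (adjusted over the list alone, 3 and 0), epidermis and cuticle 2 of 4 higher and 0 lower (adjusted over the list alone, 2 and 0), phloem 0 of 2 higher and 1 lower (adjusted over the list alone, 0 and 1), and pollen and anther 1 of 2 higher and 0 lower (adjusted over the list alone, 1 and 0). Xylem had 0 of 1 higher and 0 lower (adjusted over the list alone, 1 and 0). Hypoxia had 2 of 6 higher and 0 lower (adjusted over the list alone, 2 and 0), senescence 3 of 12 higher and 4 lower (adjusted over the list alone, 3 and 4), phenylpropanoids 3 of 6 higher and 1 lower (adjusted over the list alone, 3 and 2), cytosolic ribosomal proteins 5 of 6 higher and 0 lower (adjusted over the list alone, 5 and 0), and the cell cycle 1 of 2 higher and 0 lower (adjusted over the list alone, 1 and 0). Proton pumps had 0 of 1 higher and 0 lower (adjusted over the list alone, 0 and 0).

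Against leaf, 1838 transcripts were higher and 1172 lower in extrafloral nectaries at an adjusted p under 0.05. The median log2 fold change over all transcripts was 0.128, and rescaling by median ratios moved it to 0.00377, with 1560 higher and 1509 lower. The share that was higher, 61.1%, was 50.8% after that rescaling and 52.9% with equal upper quartiles. Median ratios centre the fold changes by design, so this does not tell which share is right.

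Floral nectaries had higher transcripts than leaf for albumin 1, a snakin-like peptide, 2 cell wall invertases, an invertase inhibitor, 2 sucrose synthases, SWEET transporters and nectar regulators. Photosynthesis transcripts were lower by far more than in the extrafloral nectaries. Albumin 1 (A1) averaged 79242 ± 1492 at pre2 and 1 ± 1 in leaf. The MYB305-like, MYB24-like and CRABS CLAW-like regulators were listed at 0 in leaf.

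Albumin 1, the most increased of the named genes, rose by 14.58 (SE 0.779, adjusted p = 2.35e-12), and the invertase inhibitor LOC100500640 by 13.56 (SE 0.84, adjusted p = 2.16e-11). The antimicrobial peptide snakin-2-like LOC100795140 was listed at 0 in leaf and averaged 28392 ± 3521 at pre2 (adjusted p = 9.69e-12). The haloacid dehalogenase-like LOC547648 rose by 11.87 (SE 0.475, adjusted p = 3.41e-14). Cell wall invertases LOC100777418 and CWINV rose by 9.65 (SE 0.444, adjusted p = 2.52e-13) and 5.79 (SE 0.208, adjusted p = 6.94e-15), sucrose synthases LOC100802045 and SS by 8.09 (SE 0.285, adjusted p = 5e-15) and 4.904 (adjusted p = 1.31e-13), and SWEET13-like LOC100810946 by 5.49 (SE 0.364, adjusted p = 5.78e-11). The SWEET family members LOC102669242 and LOC100810962, listed at 0 in leaf, averaged 1775 ± 226 and 549 ± 217 at the secretory stage (adjusted p = 2.86e-15 and 9.55e-16). Sucrose metabolism had 6 of 8 higher and 2 lower (adjusted over the list alone, 6 and 2; camera adjusted p = 0.0452 and adjusted p = 0.356 with an estimated correlation). Sugar transport had 5 of 7 higher and 1 lower (adjusted over the list alone, 5 and 1; camera adjusted p = 0.0932). The plasma membrane proton pump LOC100805218, which energizes secondary transport, rose by 2.79 (adjusted p = 1.93e-09), and the list of pumps had 1 of 1 higher and 0 lower (adjusted over the list alone, 1 and 0).

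The nectar list, of regulators, 2 invertases and a SWEET transporter, had 8 of 8 higher and 0 lower (adjusted over the list alone, 8 and 0; camera adjusted p = 0.000114 and adjusted p = 0.0755 with an estimated correlation). MYB305-like LOC100816972 averaged 7519 ± 2716 at pre1 and 11135 ± 752 at pre2 (adjusted p = 3.09e-15), and the MYB24-matched MYB98 and MYB182 5198 ± 1051 and 2905 ± 537 at pre1 (adjusted p = 1.62e-16 and 8.77e-17). The CRABS CLAW-like LOC100500026 averaged 6571 ± 1675 at pre1 (adjusted p = 4.75e-20). These were at 0 in leaf. BLADE-ON-PETIOLE-like LOC100816086 rose by 0.44 (SE 0.15, adjusted p = 0.0123), but post (111) was below leaf (166). The call was lost with median ratios (0.335, or 0.362 without photosynthesis transcripts) or equal upper quartiles (0.819). Floral organ identity had 13 of 14 higher and 0 lower (adjusted over the list alone, 13 and 0; camera adjusted p = 5.67e-06 and adjusted p = 0.0446 with an estimated correlation), among them the AGAMOUS-like LOC100776263, listed at 0 in leaf and averaging 1385 ± 99.1 at pre1 (adjusted p = 7.47e-17). Carpel and ovule genes had 4 of 4 higher and 0 lower (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00409 and adjusted p = 0.115 with an estimated correlation), epidermis and cuticle 4 of 4 higher and 0 lower (adjusted over the list alone, 4 and 0), phloem 1 of 2 higher and 0 lower (adjusted over the list alone, 1 and 0), and pollen and anther 1 of 2 higher and 0 lower (adjusted over the list alone, 1 and 0). Xylem had 1 of 1 higher and 0 lower (adjusted over the list alone, 1 and 0), but 0 higher in all 3 rescalings.

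Photosystem and antenna transcripts were lower, with a median of -8.84, and the list had 0 of 20 higher and 20 lower (adjusted over the list alone, 0 and 20; camera adjusted p = 5.97e-20 and adjusted p = 0.0446 with an estimated correlation). Calvin cycle transcripts had a median of -8.55, with 0 of 6 higher and 6 lower (adjusted over the list alone, 0 and 6; camera adjusted p = 4.17e-06 and adjusted p = 0.0446 with an estimated correlation). The chloroplast thiamine enzyme LOC100794288 stood at -12.09 (SE 0.419, adjusted p = 4.14e-15), CP29 (LOC100785415) at -10.63 (SE 0.276, adjusted p = 8.77e-17), the Rubisco small chain LOC100794277 at -10.4 (SE 0.33, adjusted p = 1.22e-15), and the photosystem I subunit LOC100800992 at -9.92 (adjusted p = 1.18e-17). Starch breakdown had 1 of 12 higher and 8 lower (adjusted over the list alone, 1 and 8; camera adjusted p = 0.00527 and adjusted p = 0.0819 with an estimated correlation), with beta-amylase BMY1_NM_001249318.1 at -4.61 (adjusted p = 1.57e-11) and the maltose-using transferase DPE2 (LOC100793021) at -3.25 (adjusted p = 4.57e-14). Starch synthesis had 2 of 5 higher and 3 lower (adjusted over the list alone, 2 and 3), with ADP-glucose pyrophosphorylase LOC100786313 at -4.39 (adjusted p = 3.69e-10) and starch synthase LOC100301883 at -3.24 (adjusted p = 3.18e-12).

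Proline dehydrogenase 2 (LOC100799876) and cytosolic glutamine synthetase GS1beta2 rose by 7.21 (adjusted p = 5.28e-13) and 4.55 (adjusted p = 2.03e-13). The amino acid and nitrogen list had 9 of 12 higher and 3 lower (adjusted over the list alone, 9 and 3). The acidic endochitinase LOC100815291 rose by 7.31 (adjusted p = 5.24e-13). Defence and nectar proteins had 4 of 7 higher and 2 lower (adjusted over the list alone, 4 and 2). The auxin response repressor IAA19 (LOC100305535) rose by 6.24 (adjusted p = 4.39e-13). The auxin list had 8 of 13 higher and 2 lower (adjusted over the list alone, 8 and 2). Pectinesterase LOC100813592 rose by 6.12 (adjusted p = 4.15e-13), within a primary wall list of 8 of 10 higher and 1 lower (adjusted over the list alone, 8 and 2). Jasmonate genes had 5 of 12 higher and 6 lower (adjusted over the list alone, 5 and 6), the receptor COI1 (LOC100779171) being at -1.78 (adjusted p = 3.23e-09). Heat shock genes had 7 of 7 higher and 0 lower (adjusted over the list alone, 7 and 0; camera adjusted p = 0.021 and adjusted p = 0.145 with an estimated correlation), and the rapid wound response 3 of 7 higher and 1 lower (adjusted over the list alone, 3 and 1). Hypoxia had 5 of 6 higher and 0 lower (adjusted over the list alone, 5 and 0). The clock gene REVEILLE 1 (LOC780539) rose by 4.02 (adjusted p = 5e-13) and ELF4-like LOC100796686 by 3.701 (adjusted p = 1.17e-09). Morning clock genes had 4 of 9 higher and 2 lower (adjusted over the list alone, 4 and 2) and evening ones 2 of 7 higher and 2 lower (adjusted over the list alone, 2 and 2). Exocytosis had 6 of 11 higher and 1 lower (adjusted over the list alone, 6 and 1), with EXO70A1 (LOC100775958) at 2.33 (adjusted p = 1.62e-10). Senescence had 7 of 12 higher and 3 lower (adjusted over the list alone, 7 and 3), and phenylpropanoids 3 of 6 higher and 2 lower (adjusted over the list alone, 3 and 2). The cell cycle had 2 of 2 higher and 0 lower (adjusted over the list alone, 2 and 0). Cytosolic ribosomal proteins had 2 of 6 higher and 0 lower (adjusted over the list alone, 2 and 0), but 0 higher and 2 lower with equal upper quartiles.

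Floral nectaries against leaf gave 3051 higher and 1763 lower transcripts. The median log2 fold change was 0.375 and was 0.105 with median ratios and −0.0226 with equal upper quartiles. The share that was higher, 63.4%, became 53.8% and 49.2%.

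**Figure D3:**
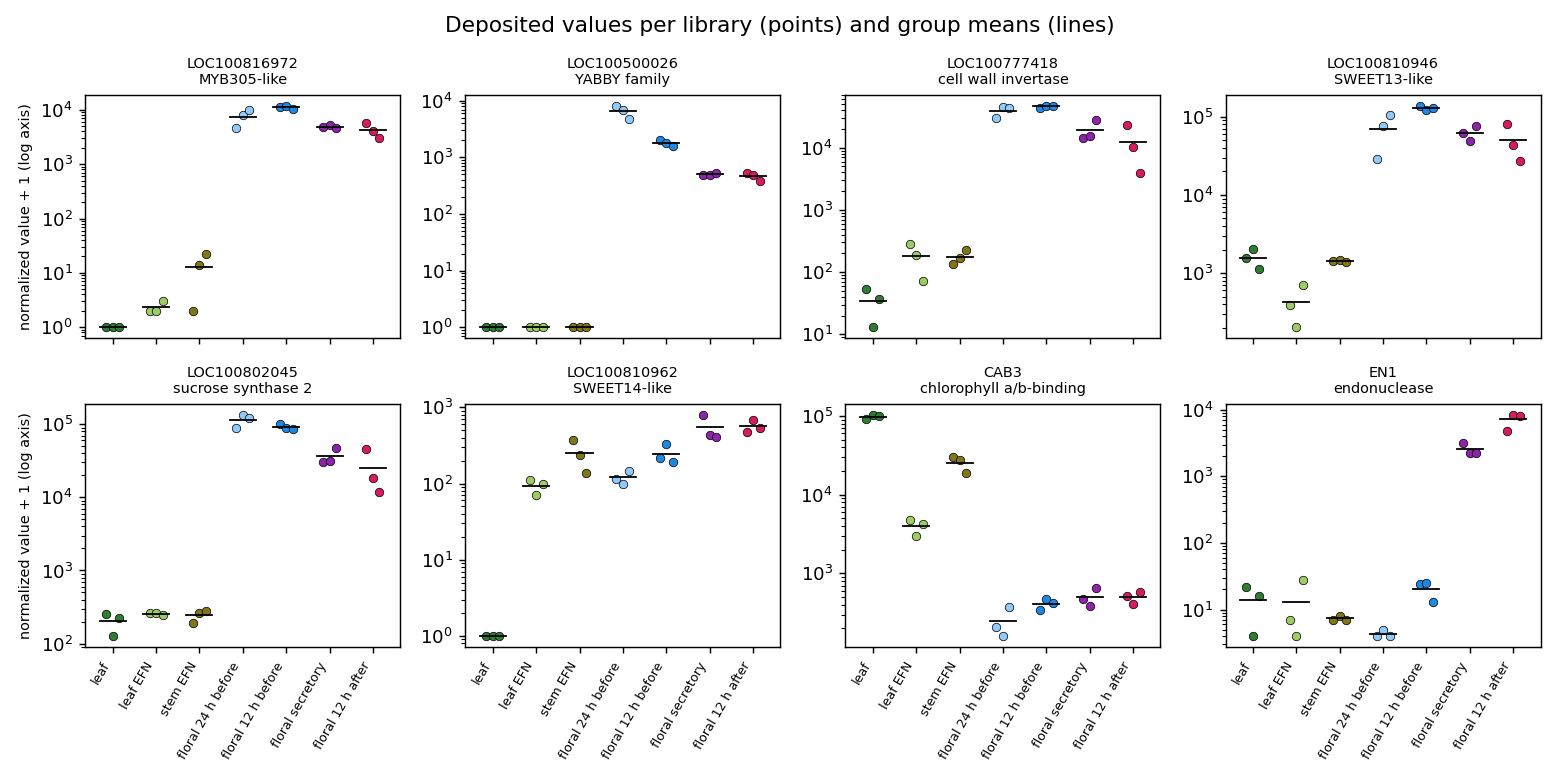
Normalized value + 1 on a log axis for 8 transcripts, across the 7 groups; each point is a library and each line the group mean. MYB305-like LOC100816972 lies at low values outside the floral nectaries and averages 11135 ± 752 at pre2.

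Between extrafloral and floral nectaries, photosynthesis transcripts, a proline-rich wall protein, a beta-amylase and a 13-lipoxygenase were higher on the extrafloral side. On the floral side were 2 cell wall invertases, an invertase inhibitor, sucrose synthase, 2 SWEET transporters, a snakin-like peptide, a glutamine synthetase and nectar regulators. The Calvin cycle and photosystem lists were higher in the extrafloral nectaries for every member. CRABS CLAW-like LOC100500026 was listed at 0 in every extrafloral library.

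On the extrafloral side, thiamine enzyme LOC100794288 stood at 9.47 (SE 0.325, adjusted p = 2.54e-15), Rubisco small chain LOC100794277 at 8.85 (SE 0.256, adjusted p = 2.54e-16), the uncharacterized LOC100305951 at 8.13 (SE 0.242, adjusted p = 3.8e-16), the proline-rich wall protein PRP3 at 8.002 (SE 0.321, adjusted p = 2.48e-14) and the Rubisco activase RCA14 at 7.98 (SE 0.393, adjusted p = 5.37e-13). Photosystems and antenna had 20 of 20 higher and 0 lower (adjusted over the list alone, 20 and 0) with a median of 6.45 (camera adjusted p = 6.92e-16 and adjusted p = 0.0681 with an estimated correlation). The Calvin cycle had 6 of 6 higher and 0 lower (adjusted over the list alone, 6 and 0) with a median of 7.19 (camera adjusted p = 4.14e-05 and adjusted p = 0.0681 with an estimated correlation). Beta-amylase BMY1_NM_001249318.1 was higher by 6.38 (adjusted p = 2.16e-15) and starch synthase LOC100301883 by 2.17 (adjusted p = 2.34e-11). Starch breakdown had 6 of 12 higher and 2 lower (adjusted over the list alone, 6 and 1; camera adjusted p = 0.0491 and adjusted p = 0.195 with an estimated correlation) and starch synthesis 3 of 5 higher and 2 lower (adjusted over the list alone, 3 and 2). The jasmonate-forming 13-lipoxygenase LOC100811820 and the receptor COI1 (LOC100779171) were higher by 3.14 (adjusted p = 2.88e-11) and 1.37 (adjusted p = 2.76e-09). The jasmonate list had 10 of 12 higher and 1 lower (adjusted over the list alone, 10 and 1; camera adjusted p = 0.00484 and adjusted p = 0.195 with an estimated correlation). Phenylpropanoids had 3 of 6 higher and 2 lower (adjusted over the list alone, 3 and 2), with coumarate 4-hydroxylase C4H at 3.37 (adjusted p = 2.46e-09), and the rapid wound response had 3 of 7 higher and 3 lower (adjusted over the list alone, 3 and 3).

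On the floral side, the invertase inhibitor LOC100500640 stood at -12.08 (SE 0.651, adjusted p = 2.05e-12), snakin-2-like LOC100795140 at -11.34 (SE 0.63, adjusted p = 3.33e-12), albumin 1 (A1) at -10.82 (SE 0.603, adjusted p = 3.48e-12), and the lipid-transfer-like LOC100500124 and LOC100306273 at -11.42 (adjusted p = 2.43e-14) and -10.84 (adjusted p = 1.64e-14). Cell wall invertases LOC100777418 and CWINV were at -7.18 (SE 0.344, adjusted p = 3.46e-13) and -4.36 (SE 0.161, adjusted p = 7.82e-15), sucrose synthase LOC100802045 at -7.74 (SE 0.221, adjusted p = 2.32e-16), SWEET13-like LOC100810946 at -6.55 (SE 0.282, adjusted p = 6.95e-14) and SWEET6b-like LOC100791284 at -8.59 (adjusted p = 5.34e-15). Sucrose metabolism had 2 of 8 higher and 6 lower (adjusted over the list alone, 2 and 6; camera adjusted p = 0.0525) and sugar transport 1 of 7 higher and 6 lower (adjusted over the list alone, 1 and 6; camera adjusted p = 0.0993). Glutamine synthetase LOC547621 was at -7.76 (adjusted p = 2.69e-12), and amino acids and nitrogen had 2 of 12 higher and 10 lower (adjusted over the list alone, 2 and 10; camera adjusted p = 0.0108 and adjusted p = 0.224 with an estimated correlation). The proton pump LOC100805218 was at -2.59 (adjusted p = 1.13e-10). Pump genes had 0 of 1 higher and 1 lower (adjusted over the list alone, 0 and 1).

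The nectar list, of regulators, 2 invertases and a SWEET transporter, had 0 of 8 higher and 8 lower (adjusted over the list alone, 0 and 8; camera adjusted p = 3.91e-05 and adjusted p = 0.0681 with an estimated correlation), with the BLADE-ON-PETIOLE match LOC100816086 at -1.38 (SE 0.116, adjusted p = 1.7e-09), MYB305-like LOC100816972 at -10.5 (adjusted p = 7.94e-16), MYB98 at -9.35 (adjusted p = 3.5e-17) and MYB182 at -9.56 (adjusted p = 4.46e-18). Floral organ identity had 0 of 14 higher and 14 lower (adjusted over the list alone, 0 and 14; camera adjusted p = 5.39e-07 and adjusted p = 0.0209 with an estimated correlation) and carpel and ovule 0 of 4 higher and 4 lower (adjusted over the list alone, 0 and 4; camera adjusted p = 0.00484 and adjusted p = 0.159 with an estimated correlation). Auxin genes had 2 of 13 higher and 10 lower (adjusted over the list alone, 2 and 10), with IAA19 (LOC100305535) at -7.98 (adjusted p = 2.54e-16). Senescence had 2 of 12 higher and 8 lower (adjusted over the list alone, 2 and 8), with the nuclease EN1 at -4.59 (adjusted p = 4.58e-10). Heat shock had 0 of 7 higher and 6 lower (adjusted over the list alone, 0 and 6; camera adjusted p = 0.0421 and adjusted p = 0.195 with an estimated correlation), morning clock genes 2 of 9 higher and 7 lower (adjusted over the list alone, 2 and 7) and evening ones 0 of 7 higher and 6 lower (adjusted over the list alone, 0 and 6), REVEILLE 1 (LOC780539) being at -3.36 (adjusted p = 1.18e-13).

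In this comparison 2060 transcripts were higher and 2973 lower in extrafloral nectaries, 5033 in all. With a 2-fold minimum they were 2978, against 3237 for floral nectaries and 1557 for extrafloral nectaries against leaf, and numbers of libraries differ between these comparisons. A total of 4604 were called with the secretory stage alone in place of the 4 stages. The median was −0.241, moving to −0.0929 with median ratios and 0.0556 with equal upper quartiles, and the share higher went from 40.9% to 46.8% and 52.3%.

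**Figure D4:**
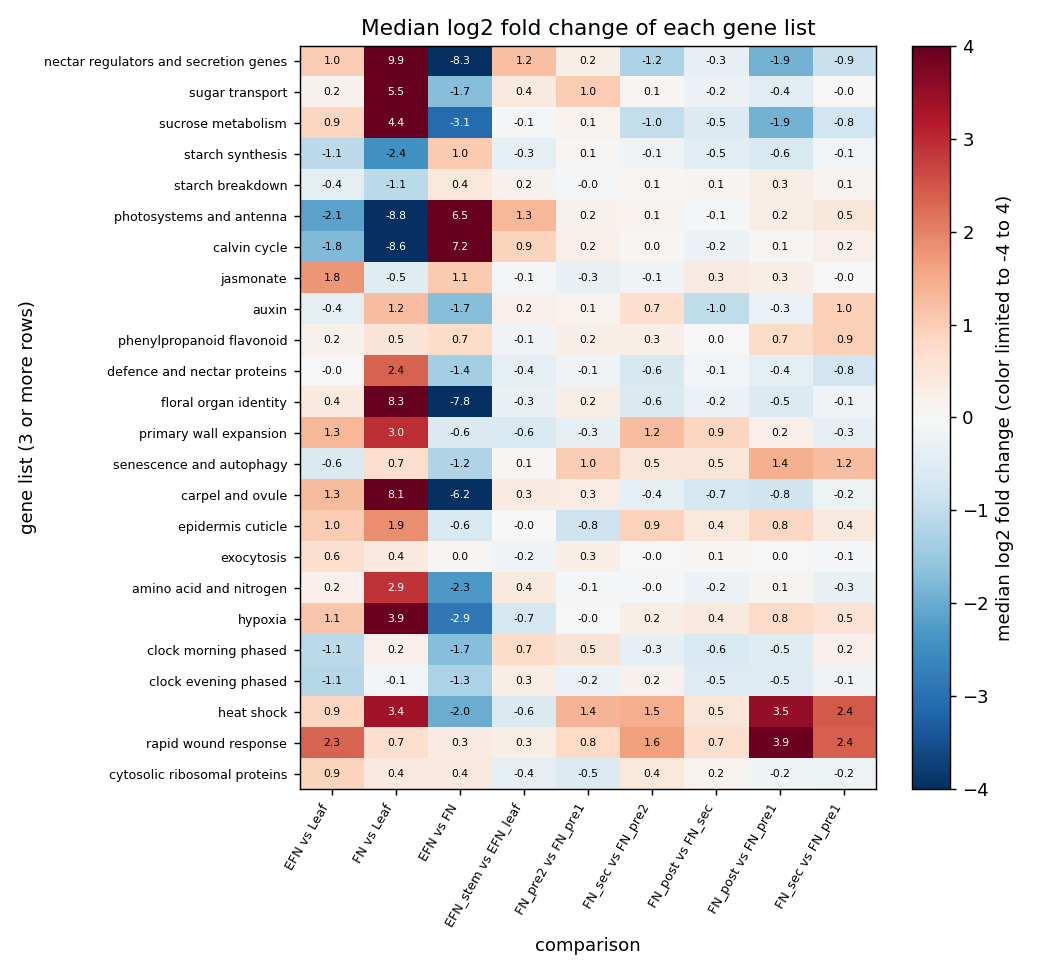
Median log2 fold change of 24 gene lists, in rows, in 9 comparisons, in columns, with the value in each cell and the colour limited to the range from −4 to 4. Photosystem and antenna genes have medians of -2.13 in extrafloral nectaries and -8.84 in floral nectaries against leaf.

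Transcripts that changed against leaf in both nectary types numbered 1208 higher in both and 715 lower in both, while 459 went in opposite directions. Among the shared higher transcripts were SWEET14-like LOC100810962, the cell wall invertases LOC100777418 and CWINV, sucrose synthase SS, TIFY10A (LOC100801449) and VAMP726-like LOC100804314. Lower in both were photosystem and Calvin cycle genes such as LOC732655. The opposite ones included SWEET13-like LOC100810946 and BLADE-ON-PETIOLE-like LOC100816086, with falls mainly in leaf EFN. The first lost its extrafloral call without leaf library 2 (0.146), the second its floral call with median ratios (0.335).

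Independent lists of these sizes would share 883 higher and 325.3 lower transcripts by chance, but the same leaf libraries serve both comparisons, so part of the excess may come from the shared controls. In simulations with those shared controls and no true change 0 were shared, but few calls arise at all there. The same sign was found for 66.86% of transcripts against 75.91% simulated. The correlation of the fold changes was 0.4997 against 0.7302 simulated from the shared controls alone, while their covariance was 1.26 against 0.05726. The 3 leaf libraries were not divided between the comparisons, since one part would hold a single library. Each of the 6 nectary tissues had the same change against leaf for 606 higher and 367 lower transcripts. The share higher was 62.8% for the overlap and 62.3% for the 6 tissues, and 49.9% and 46% with median ratios. Called counts against leaf ran from 2209 in stem EFN to 4593 in post. Shares higher ran from 60.5% in leaf EFN to 64.5% in the secretory stage, which the apparent filter may favour. With median ratios they were 51.8% and 54.9%.

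Stem EFN had higher chlorophyll-binding, abscisic stress and amino acid permease transcripts than leaf EFN, and lower osmotin-like and ferritin transcripts. The chlorophyll-binding CAB3 was the photosystem member with the smallest adjusted p. BLADE-ON-PETIOLE-like LOC100816086 was also higher in stem EFN.

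CAB3 rose by 2.68 (SE 0.273, adjusted p = 2.19e-05), LOC100815789 by 2.75 (SE 0.36, adjusted p = 0.000196) and LOC100808379 by 2.11 (adjusted p = 9.96e-05). The photosystem list had 17 of 20 higher and 0 lower (adjusted over the list alone, 19 and 0) with a median of 1.32 (camera adjusted p = 7.91e-24 and adjusted p = 0.0723 with an estimated correlation). The Calvin cycle list had 0 of 6 higher and 0 lower (adjusted over the list alone, 2 and 0; camera adjusted p = 0.00801 and adjusted p = 0.329 with an estimated correlation). The abscisic stress ripening-like LOC732594 rose by 2.94 (SE 0.423, adjusted p = 0.000456), amino acid permease LOC100818535_XM_014771190.1 by 2.72 (SE 0.414, adjusted p = 0.000941), and the wax-forming LOC100785983 by 1.598 (adjusted p = 0.00291). Beta-amylase BMY1_NM_001249318.1 rose by 2.06 (adjusted p = 0.00201), and not with a fit to only these libraries (0.0785). Osmotin-like OLPa stood at -4.24 (SE 0.525, adjusted p = 0.000113), FERRITIN at -3.02 (SE 0.568, adjusted p = 0.00372), acidic endochitinase LOC100815291 at -2.28 (adjusted p = 0.00532) and the nitrate transporter-like LOC100812906 at -3.43 (adjusted p = 0.00137), or 0.0731 in that smaller fit. Sugar transport had 3 of 7 higher and 0 lower (adjusted over the list alone, 4 and 1), primary wall 0 of 10 higher and 0 lower (adjusted over the list alone, 0 and 0; camera adjusted p = 0.0474 and adjusted p = 0.492 with an estimated correlation), and heat shock 0 of 7 higher and 2 lower (adjusted over the list alone, 0 and 3; camera adjusted p = 0.00422 and adjusted p = 0.13 with an estimated correlation).

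The nectar list had 5 of 8 higher and 0 lower (adjusted over the list alone, 5 and 0; camera adjusted p = 0.000539 and adjusted p = 0.13 with an estimated correlation). BLADE-ON-PETIOLE-like LOC100816086 rose by 1.21 (SE 0.19, adjusted p = 0.00124), with 0.0566 in a fit to only these libraries. SWEET13-like LOC100810946 and SWEET14-like LOC100810962 rose by 1.92 (adjusted p = 0.0189) and 1.32 (adjusted p = 0.0221). These calls were lost without leaf EFN library 2 (0.142 and 0.136), stem EFN library 1 (0.0672 and 0.126) or stem EFN library 2 (0.0529 and 0.0607). MYB98 rose by 1.602 (adjusted p = 0.0168), lost without leaf EFN library 2 (0.119) or stem EFN library 2 (0.0822). MYB305-like LOC100816972 rose by 1.89 (adjusted p = 0.0473), lost without any of leaf EFN libraries 1 (0.12), 2 (0.172) and 3 (0.0536) or stem EFN libraries 2 (0.17) and 3 (0.157). MYB182, listed at 0 in leaf EFN, averaged 1.67 ± 1.53 in stem EFN (adjusted p = 0.0437), lost without any of leaf EFN libraries 1 (0.09), 2 (0.133) and 3 (0.0704) or stem EFN libraries 2 (0.186) and 3 (0.1). With stem EFN libraries 2 and 3 left out together, an alternative chosen after seeing the data, LOC100816972 stood at −0.195 (adjusted p = 0.798), and MYB98, MYB182 and LOC100810946 had adjusted p = 0.6, 1 and 0.105. Cell wall invertases LOC100777418 and CWINV did not pass (adjusted p = 0.912 and 0.935).

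Stem EFN had 178 higher and 163 lower transcripts than leaf EFN, 341 in all; the count was 100 without leaf EFN library 2, 139 without stem EFN library 1 and 547 without stem EFN library 3. The authors' deposited table called 131, of which 113 were called here.

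From pre1 to pre2 the floral nectary gained transcripts of a ferritin, a seed maturation protein, ELIP, 2 small heat shock proteins, the beta-amylase BMY2 and the sugar transporters LOC100305842 and STP1. Those of the CRABS CLAW match, 2 asparagine synthetases, a calreticulin, an expansin and a pectinesterase were lower. MYB305-like, invertase and SWEET13-like transcripts were high at both stages and did not pass the test.

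Fatty acid desaturase LOC100795628 rose by 4.44 (SE 0.402, adjusted p = 1.66e-06), the co-chaperone match LOC102667357 by 4.34 (SE 0.425, adjusted p = 2.61e-06), seed maturation protein LOC547921 by 4.07 (adjusted p = 0.00113), ferritin SFERH-2 by 3.97 (SE 0.485, adjusted p = 2.03e-05) and the early light-induced ELIP by 3.82 (adjusted p = 5.24e-05). Small heat shock proteins LOC100499658 and LOC100500666 rose by 4.15 (adjusted p = 5.29e-05) and 3.78 (adjusted p = 2.75e-05), in a heat shock list of 4 of 7 higher and 0 lower (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00046 and adjusted p = 0.109 with an estimated correlation). The SWEET family LOC100305842 and monosaccharide transporter STP1 rose by 1.72 (adjusted p = 0.000512) and 1.39 (adjusted p = 0.00215). Beta-amylase BMY2 rose by 1.77 (adjusted p = 0.000176). SLR1 (IAA14) and IAA16-like LOC100803986 rose by 2.62 (adjusted p = 0.00049) and 1.21 (adjusted p = 0.000501). WRKY33-matched LOC106797757 rose by 2.67 (adjusted p = 9.61e-06). REVEILLE 1 (LOC780539) rose by 1.17 (adjusted p = 0.00246). Morning clock genes had 1 of 9 higher and 0 lower (adjusted over the list alone, 1 and 0) and evening ones 0 of 7 higher and 0 lower (adjusted over the list alone, 0 and 0).

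CRABS CLAW-like LOC100500026 stood at -1.82 (SE 0.2, adjusted p = 8.07e-06), from 6571 ± 1675 to 1825 ± 236. Asparagine synthetases AS1 and AS2 were at -2.88 (adjusted p = 0.000925) and -2.69 (adjusted p = 0.00108), calreticulin LOC100037475 at -2.83 (SE 0.345, adjusted p = 2.03e-05), the BIG PETAL match LOC100306638, which limits petal size, at -3.31 (adjusted p = 0.000808), expansin LOC100820154 at -2.5 (adjusted p = 0.000434) and pectinesterase LOC100800971 at -2.16 (adjusted p = 0.000844). BLADE-ON-PETIOLE-like LOC100816086 rose by 0.59 (adjusted p = 0.0342), lost without pre1 libraries 1 (0.104) or 2 (0.151) or pre2 libraries 2 (0.0631) or 3 (0.186). SWEET13-like LOC100810946 did not pass (adjusted p = 0.105), but did without pre1 library 3 (0.0389). LOC100816972, LOC100777418, CWINV, MYB182 and MYB98 did not pass either (adjusted p = 0.437, 0.791, 0.6, 0.405 and 0.182). The nectar list had 1 of 8 higher and 1 lower (adjusted over the list alone, 1 and 1) and senescence 5 of 12 higher and 2 lower (adjusted over the list alone, 5 and 2).

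Between pre1 and pre2, 789 transcripts were higher and 448 lower, 1237 in all, with 617 without pre1 library 1 and 695 without pre2 library 2. The share higher was 63.8% and was 50.2% with equal upper quartiles. The authors' deposited table called 1199, of which 842 were called here.

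At the secretory stage nuclease, metacaspase, ribonuclease, auxin transport and NAC transcripts were higher than at pre2. CRABS CLAW-like and MYB24-like regulators and an APETALA2-like transcript were lower. In the lists for heat shock and for the rapid wound response, 5 of 7 members each were higher, and the camera calls of both were lost with an estimated correlation (adjusted p = 0.149).

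The nuclease EN1, of cell death and senescence, rose by 7.002 (SE 0.578, adjusted p = 7.92e-08), metacaspase-9 (LOC100781510) by 5.26 (SE 0.395, adjusted p = 3.74e-08), NAC72 (LOC100811301) by 4.87 (adjusted p = 1.2e-05) and ribonuclease 1 (LOC100305644) by 4.61 (adjusted p = 1.69e-05). Senescence had 4 of 12 higher and 1 lower (adjusted over the list alone, 5 and 1; camera adjusted p = 0.0264 and adjusted p = 0.495 with an estimated correlation). P450 LOC100785420 rose by 5.55 (SE 0.42, adjusted p = 3.82e-08) and the transmembrane LOC100813958 by 4.91 (adjusted p = 2.63e-08). Auxin efflux carrier LOC100802247_XM_006605305.2 and auxin transporter LOC100810532 rose by 4.498 (SE 0.195, adjusted p = 1.47e-11) and 5.02 (adjusted p = 6.25e-06). Auxin had 4 of 13 higher and 0 lower (adjusted over the list alone, 4 and 0; camera adjusted p = 0.029 and adjusted p = 0.399 with an estimated correlation). Xyloglucan-modifying LOC102661404 and LOC100785313 rose by 4.13 (adjusted p = 0.000794) and 3.44 (adjusted p = 1.29e-05). Primary wall had 4 of 10 higher and 1 lower (adjusted over the list alone, 5 and 1; camera adjusted p = 0.029 and adjusted p = 0.495 with an estimated correlation). Beta-amylases BMY1_NM_001249318.1 and BMY2 rose by 3.49 (adjusted p = 1.26e-06) and 1.3 (adjusted p = 0.00185), the SWEET family LOC100305842 by 1.63 (adjusted p = 0.000573), STP1 by 1.61 (adjusted p = 0.000523) and amino acid permease LOC100818535_XM_014771190.1 by 3.48 (adjusted p = 7.18e-06). Oxophytodienoate reductase LOC100818208 rose by 1.23 (adjusted p = 0.000847). Heat shock had 5 of 7 higher and 0 lower (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00157 and adjusted p = 0.149 with an estimated correlation), with HSP83 (LOC100811234) at 1.204 (adjusted p = 0.000129). Rapid wound response had 5 of 7 higher and 0 lower (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00132 and adjusted p = 0.149 with an estimated correlation), with STF-3 at 3.81 (adjusted p = 9.37e-05).

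The nectar list had 0 of 8 higher and 4 lower (adjusted over the list alone, 0 and 7; camera adjusted p = 0.000521 and adjusted p = 0.149 with an estimated correlation). LOC100500026 stood at -1.87 (SE 0.2, adjusted p = 2.19e-06), MYB98 at -2.04 (SE 0.375, adjusted p = 0.00072) and MYB182 at -2.104 (adjusted p = 0.000185). Invertase CWINV was at -0.93 (adjusted p = 0.0168), lost without pre2 library 1 (0.0566) or secretory libraries 1 (0.0633) or 2 (0.0704). MYB305-like LOC100816972, LOC100810946, LOC100777418 and LOC100816086 did not pass (adjusted p = 0.136, 0.103, 0.101 and 0.617). A fit to only these libraries gave 1.48e-05, 0.00159 and 0.000753 for the first 3, so spread in other groups decides them. Sucrose synthase SS and sucrose-phosphatase LOC100796915 were at -1.06 (adjusted p = 0.00931) and -1.199 (adjusted p = 0.00165). Sucrose metabolism had 1 of 8 higher and 4 lower (adjusted over the list alone, 1 and 6; camera adjusted p = 0.0324 and adjusted p = 0.445 with an estimated correlation). APETALA2-like LOC100797238 was at -2.43 (SE 0.276, adjusted p = 4.36e-06) and early nodulin-like LOC100795901 at -2.24 (adjusted p = 0.000426).

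This step had 800 higher and 557 lower transcripts, 1357 in all. The count was 865 without pre2 library 3, 868 without secretory library 1 and 833 without secretory library 2. Fitting only the libraries of this step called more, as given below. The authors' deposited table called 1900, of which 1044 were called here. Of 358 transcripts called in both this step and the one before, 276 went the same way and 82 the opposite way, and noise in the shared pre2 libraries favours the latter.

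After secretion, calcium pump, nitrate reductase, alpha-amylase and jasmonate repressor transcripts rose, and boron transporter, growth-regulating factor, inositol transporter and beta-amylase transcripts fell. BLADE-ON-PETIOLE-like LOC100816086 fell as well. MYB and CRABS CLAW-like regulators stayed near their secretory values and did not pass the test.

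The calcium-transporting ATPase LOC100793918 rose by 3.02 (SE 0.484, adjusted p = 0.00091), MYB-like LOC100798848 by 2.76 (SE 0.493, adjusted p = 0.00242), nitrate reductase INR2 by 2.803 (adjusted p = 0.00529), alpha-amylase LOC100815664 by 2.604 (adjusted p = 0.00428) and the caleosin-like LOC100306686 by 2.77 (adjusted p = 0.00957), the last lost without secretory library 2 (0.0644), post library 2 (0.0643) or post library 3 (0.0609). TIFY10A (LOC100801449) and JAZ1 (LOC100306332) rose by 2.59 (SE 0.357, adjusted p = 0.000277) and 1.97 (adjusted p = 0.00117). Jasmonate had 3 of 12 higher and 0 lower (adjusted over the list alone, 4 and 0; camera adjusted p = 0.0149 and adjusted p = 0.322 with an estimated correlation). WRKY47 (LOC100783661) and ribonuclease 2 (LOC100306447) rose by 2.16 (adjusted p = 0.000138) and 1.18 (adjusted p = 0.00252). Senescence had 2 of 12 higher and 0 lower (adjusted over the list alone, 3 and 0; camera adjusted p = 0.0196 and adjusted p = 0.412 with an estimated correlation). Boron transporter LOC100776705 stood at -3.21 (SE 0.326, adjusted p = 1.04e-05), beta-amylase BMY1_NM_001249318.1 at -2.82 (SE 0.353, adjusted p = 8.94e-05), growth-regulating factor LOC100814842 at -2.56 (adjusted p = 3.87e-05), inositol transporter LOC100815588 at -2.37 (adjusted p = 0.000277), zinc finger LOC100817333 at -2.29 (adjusted p = 0.000472) and amino acid permease LOC100818535_XM_014771190.1 at -2.47 (adjusted p = 0.00135). SLR1 (IAA14) was at -3.18 (adjusted p = 0.000277). Auxin had 0 of 13 higher and 3 lower (adjusted over the list alone, 1 and 9; camera adjusted p = 0.00071 and adjusted p = 0.189 with an estimated correlation).

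BLADE-ON-PETIOLE-like LOC100816086 stood at -1.46 (SE 0.19, adjusted p = 0.000138), from 307 ± 25.7 to 111 ± 8.89. CWINV was at -1.07 (adjusted p = 0.0205), lost without secretory library 3 (0.112), post library 2 (0.0912) or post library 3 (0.176), and SS at -1.32 (adjusted p = 0.00623), lost without post library 3 (0.0561). MYB98, MYB182, LOC100500026, LOC100816972, LOC100810946 and LOC100777418 did not pass (adjusted p = 0.836, 0.896, 0.847, 0.883, 0.713 and 0.431). The nectar list had 0 of 8 higher and 2 lower (adjusted over the list alone, 0 and 2). Primary wall had 0 of 10 higher and 0 lower (adjusted over the list alone, 4 and 0; camera adjusted p = 0.0149 and adjusted p = 0.412 with an estimated correlation), morning clock genes 0 of 9 higher and 1 lower (adjusted over the list alone, 0 and 3; camera adjusted p = 0.0217 and adjusted p = 0.468 with an estimated correlation), heat shock 0 of 7 higher and 0 lower (adjusted over the list alone, 2 and 0; camera adjusted p = 0.0244 and adjusted p = 0.322 with an estimated correlation) and rapid wound response 1 of 7 higher and 0 lower (adjusted over the list alone, 3 and 0; camera adjusted p = 0.0196 and adjusted p = 0.322 with an estimated correlation).

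The step had 167 higher and 197 lower transcripts, 364 in all; the count was 212, 185 and 189 without secretory libraries 1, 2 and 3, and 604, 172 and 136 without post libraries 1, 2 and 3. The authors' deposited table called 627, of which 281 were called here. Of 174 transcripts called in this step and the one before, 107 went the same way and 67 the opposite way, with the same limit from the secretory libraries.

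Over the whole series, from pre1 to post, 8 of 12 senescence genes, 6 of 7 heat shock genes and the sugar carriers LOC100305842 and STP1 rose. The cell wall invertases LOC100777418 and CWINV and sucrose synthase SS fell, and 6 of 8 members of the nectar list were lower, these invertases among them, the call of LOC100777418 being lost without post library 3 (0.0551). The nuclease EN1 rose most among the named genes.

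EN1 rose by 10.66 (SE 0.578, adjusted p = 7.64e-11), from 3.33 ± 0.577 to 7188 ± 1993, and ribonuclease 1 (LOC100305644) by 7.85 (adjusted p = 4.35e-09). Senescence had 8 of 12 higher and 1 lower (adjusted over the list alone, 8 and 1; camera adjusted p = 0.00494 and adjusted p = 0.609 with an estimated correlation). Small heat shock proteins HSP18.5-C, LOC100499658 and LOC100500666 rose by 9.09 (SE 0.497, adjusted p = 7.97e-11), 7.76 (adjusted p = 2.64e-09) and 7.17 (adjusted p = 9.98e-10). Heat shock had 6 of 7 higher and 0 lower (adjusted over the list alone, 7 and 0; camera adjusted p = 9.63e-05 and adjusted p = 0.0643 with an estimated correlation). WRKY33-matched LOC106797757 rose by 6.06 (SE 0.299, adjusted p = 3.01e-11). Rapid wound response had 6 of 7 higher and 0 lower (adjusted over the list alone, 6 and 0; camera adjusted p = 0.00104 and adjusted p = 0.207 with an estimated correlation). The transporter match LOC100500595 and membrane protein LOC100819509 rose by 8.73 (SE 0.643, adjusted p = 3.48e-09) and 8.68 (adjusted p = 1.12e-09). Auxin efflux carrier LOC100802247_XM_006605305.2 rose by 4.73 (adjusted p = 5.95e-12), the SWEET family LOC100305842 by 4.24 (adjusted p = 1.55e-09), STP1 by 3.47 (adjusted p = 1.38e-08), BMY2 by 3.27 (adjusted p = 1.33e-08), neutral invertase LOC100785091 by 2.56 (adjusted p = 3.15e-07) and proline dehydrogenase PDH by 3.02 (adjusted p = 2.35e-05).

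The nectar list had 0 of 8 higher and 6 lower (adjusted over the list alone, 0 and 6) with a median of -1.88 (camera adjusted p = 0.00285 and adjusted p = 0.253 with an estimated correlation). CWINV stood at -1.78 (SE 0.264, adjusted p = 1.66e-05), SS at -2 (adjusted p = 6.33e-06), LOC100816086 at -1.02 (adjusted p = 0.000188) and LOC100777418 at -1.98 (adjusted p = 0.00604), lost without post library 3 (0.0551). Phosphoglucomutase LOC100778321, which links sucrose use and starch, was at -2.38 (SE 0.359, adjusted p = 2.04e-05), amino acid permease LOC100777963 at -1.83 (adjusted p = 6.21e-06) and BEL1-like LOC100812360 at -1.302 (adjusted p = 4.85e-05). The MYB305-like LOC100816972 and SWEET13-like LOC100810946 did not pass (adjusted p = 0.246 and 0.463). REVEILLE 8 (LOC100783482) and ELF4-like LOC100796686 were at -1.71 (adjusted p = 2.06e-05) and -1.66 (adjusted p = 0.00121). Sucrose metabolism had 1 of 8 higher and 5 lower (adjusted over the list alone, 1 and 5). From pre1 to the secretory stage, the nectar list had 0 of 8 higher and 4 lower (adjusted over the list alone, 1 and 4; camera adjusted p = 0.0349 and adjusted p = 0.518 with an estimated correlation), auxin 5 of 13 higher and 1 lower (adjusted over the list alone, 5 and 1; camera adjusted p = 0.0289 and adjusted p = 0.391 with an estimated correlation), heat shock 7 of 7 higher and 0 lower (adjusted over the list alone, 7 and 0; camera adjusted p = 0.000137 and adjusted p = 0.0722 with an estimated correlation) and rapid wound response 5 of 7 higher and 0 lower (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00521 and adjusted p = 0.357 with an estimated correlation).

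From pre1 to post 1643 transcripts were higher and 1682 lower, and from pre1 to the secretory stage 1602 and 1315. The F test over the 4 stages called 3617, or 56.95%. Of these, 1298 were highest at pre1, 574 at pre2, 631 at the secretory stage and 1114 at post.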

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

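The tests on floral traces and on photosynthesis transcripts were chosen only after the results were seen; the one on time of day was written before.

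Of the 459 transcripts called in opposite directions against leaf, 2 are genes named in both comparisons. For these the difference between nectary types was tested directly. The BLADE-ON-PETIOLE match LOC100816086 stood at −0.937 (SE 0.164) in extrafloral and 0.442 (SE 0.15) in floral nectaries, a difference of −1.38 (SE 0.116, adjusted p = 1.7e-09). Its floral rise was not called with median ratios (0.335) or equal upper quartiles (0.819), so its opposite directions depend on the scaling. Its fall lay mainly in leaf EFN, and post (111) lay below leaf (166). SWEET13-like LOC100810946 stood at −1.06 (SE 0.398) and 5.49 (SE 0.364), a difference of −6.55 (SE 0.282, adjusted p = 6.95e-14). Its fall lay mainly in leaf EFN (429, with 1435 in stem EFN and 1577 in leaf). The call was lost without leaf library 2 (0.146), among others given above. No biological explanation was tested for either.

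Of 358 transcripts called in both of the first floral steps, 82 reversed direction. Both steps use the pre2 libraries, whose noise alone pushes towards opposite signs, and no count expected from that was computed. Stages lie 12 h apart, so the hour of sampling is a candidate, and it predicted morning clock genes to be lower at pre2 than at pre1. Their median over 9 transcripts was instead 0.516 (SE of the mean 0.176), above the bound of −0.5 set beforehand. This argues against time of day as predicted for these genes. In the next step the median was −0.318, again opposite. For 7 evening clock genes the steps gave −0.228 (SE of the mean 0.322) and 0.178 (0.228), too near 0 to tell. From the secretory stage to post, morning genes had −0.625 (0.153), with 1 of 9 higher, as the hour would give. Evening genes had −0.508 (0.119), with 1 of 7 higher, which it would not. For that step and the 82 transcripts time of day and floral development stay open. Pre1 and the secretory stage share an hour, 24 h apart, so their 2917 calls argue against the hour there.

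Stem EFN libraries 2 and 3 held low values of transcripts that are abundant in floral nectaries. A first set of 27 transcripts gave rank correlations with the floral mean of 0.602 and 0.302, the lower one under the bound of 0.5 that had been set for carried-over floral RNA or reads. Because most of these values lie near the floor, with medians of 3 and 2, a second set of 26 abundant transcripts was chosen after that result and gave 0.887 and 0.919, against at most 0.649 in the other 7 nonfloral libraries. In 12 of these 26 both libraries stood above the other 7, but were picked for such values, so this is no test. A wider set of 49 gave 0.837 and 0.689. The sets disagree and the later ones were chosen knowing the first, so carry-over cannot be told apart from low expression in the stem nectary. In stem EFN library 1, 10 of the first 27 were above 0, but they had been chosen as near 0 there, so this count favours neither. CRABS CLAW-like LOC100500026 was at 0 in both libraries, and leaving both out ended the stem EFN rise of MYB305-like LOC100816972, which then stood at −0.195.

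Photosynthesis transcripts of the extrafloral nectaries lay below leaf and far above the floral nectaries, at a median of 14.6% of leaf in leaf EFN and 35.3% in stem EFN over 26 transcripts. The authors' normalization was tested by rescaling, and the median log2 fold change of −2.08 stayed at −2.18 or lower, which argues against it as the cause. Leaf blade cells mixed in at a single share would give each transcript the same ratio to leaf. In leaf EFN the log2 ratios spanned 4.18, or 10.3 standard errors of the difference, from 3.42% of leaf for LOC100800351 to 70% for RCAALPHA, which argues against such cells as the whole cause. For stem EFN the span was 1.88, short of the bound of 2 set for this test, so leaf blade cells cannot be told apart there from photosynthesis of the nectary itself.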

How the results depend on the processing

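Alternatives chosen only after the data were seen were robust moderation, equal upper quartiles, both sets of extrafloral libraries left out together, and list membership by description. Among named genes, 4188 of 4425 values with a library left out kept their direction and side of the threshold, 234 lost and 3 gained the call; under other alternatives 5891 of 6139 did, 239 lost and 8 gained it, and 1 reversed. Of 49 camera calls among 216 list tests, 4 were kept and 45 lost with an estimated correlation, while 46 were kept with the replicate block. Of 6612 counts of list members, 6083 stayed within 1.5 times. Low values rest on few reads, and 2-fold changes were recovered for 46.3% to 71.6% of simulated transcripts. Count models were not run, since the values are normalized.

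With only the libraries compared in the fit, the counts were 66 for stem against leaf EFN, 2691 for the secretory stage against pre2, 679 for post against the secretory stage, 1199 for stem EFN against leaf and 567 for the 6 tissues; the cause was not tested. An adjusted p under 0.01 gave, by its stricter threshold, 102 for stem against leaf EFN, 597 for pre2 against pre1, 688 and 156 for the next steps, 1325 for stem EFN against leaf and 605 for the 6 tissues. A 2-fold minimum gave, by construction, 1557 for extrafloral nectaries against leaf, 2978 against floral nectaries, 709 for pre2 against pre1, 772 for the secretory stage against pre2, 2086 for post and 1714 for the secretory stage against pre1, 1799 for leaf EFN and 1261 for stem EFN against leaf, 974 for the overlap and 543 for the 6 tissues. Leaving out stem EFN libraries 2 and 3 leaves a single library, assumed to vary like the other groups, and gave 826 for stem EFN against leaf, 429 for the 6 tissues, and a reversed −0.195 for LOC100816972 in stem against leaf EFN. Leaving out both extrafloral libraries numbered 3 gave 671 for stem against leaf EFN; the cause was not tested. Leaving out single libraries gave 100 to 547 for stem against leaf EFN, 617 to 1338 for pre2 against pre1, 833 to 1056 for the secretory stage against pre2 and 136 to 604 for post against the secretory stage; the cause was not tested.

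With the replicate block the counts were 2930, 4782 and 5004 for the 3 main comparisons and 301 for stem against leaf EFN; replicate numbers do not pair the libraries, since 3 of 21 were closest to their own number, with a mean correlation of −0.0193. The block ended 1 camera call each for floral nectaries against leaf, extrafloral against floral nectaries, and stem against leaf EFN.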

Other observations

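The counts of relabelled splits below were planned, while their expected outcomes were written only after the results were seen.

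Relabelled splits of the libraries asked whether chance could give counts as large. For extrafloral nectaries against leaf only the real split, 1 of 84, called as many as 3010, the highest other giving 2281, so chance can be excluded. With the same limit, the real split stood alone at 1 of 100 in further tests. These were floral nectaries against leaf (4814 against 3021) and extrafloral against floral nectaries (5033 against 3900). The F test over stages (3617 against 2221) and the 6 nectary tissues against leaf (973 against 316) gave the same rank. For changes shared by both nectary types, 5 of 100 splits gave as many as 1923, the highest giving 2565, so chance is not excluded. Mixed tissues can carry real differences into both lists, so this is a poor test. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, and the real split was the highest in each. The real and highest other counts were 341 and 224 for stem against leaf EFN, and 1237, 1357, 364, 3325 and 2917 against 0 for pre2 against pre1, the secretory stage against pre2, post against the secretory stage, post against pre1 and the secretory stage against pre1. Against leaf they were 2980 and 7 for leaf EFN, 2209 and 22 for stem EFN, 4228 and 2 for pre1, 4351 and 0 for pre2, 4502 and 0 for the secretory stage, and 4593 and 1 for post.

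With list membership taken from descriptions, an alternative chosen after the data were seen, photosystem and antenna genes had 22 of 23 lower and 1 higher in extrafloral nectaries against leaf, with a median of −2.08, and 23 of 23 lower in floral nectaries, with −8.19. That membership also changed camera results in extrafloral nectaries against leaf. Jasmonate genes had 11 of 18 higher and 3 lower (camera adjusted p = 0.0375, against 0.192 with the curated list), phenylpropanoid genes 19 of 28 and 3 (0.0091 against 0.87), and cytosolic ribosomal proteins 77 of 97 and 2 (1.83e-08 against 0.145). Morning clock genes were no longer called (0.254 against 0.0136), nor were evening ones (0.254 against 0.0395). With an estimated correlation the first 3 were lost (0.64, 0.616 and 0.681).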
